A study of Mus musculus with 10 samples.

How the data were processed

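Liver RNA of 5 female mice heterozygous for Gyk and 5 female wildtype mice was measured, per the labels at 23 weeks of age, after a diet with 4% fat until 11 weeks and 6% fat from then on. Total RNA was amplified and labelled with biotin for Illumina bead arrays, per the labels. The deposited values were linear bead intensity, 1 value for each of 24048 probes and each sample, and the labels name BeadStudio 1.5.1.3 as the software that made them. About 31.1% to 33.1% of each array's values were below 0, so a background had been subtracted. The scale of the values was settled from the values. Whether and how the authors normalized the arrays to each other stayed unknown, and the arrays differed in their medians and quantiles, so no centring or quantile step had come last. The median intensity was 21.1, 14, 16.3, 15.4 and 16.6 in Gyk heterozygous replicates 1 to 5, and 24, 18, 15.3, 17.5 and 18.3 in wildtype replicates 1 to 5. Replicates were numbered in the order of the labels, which carries no meaning.

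A second deposited table holds un-normalized intensity and detection values in 80 columns, 8 for each of 10 arrays. Its columns are named by chip and position, on 2 chips with 8 and 2 arrays, and no label ties a position to a sample, so the 80 columns were not used here. For this reason the chip as a block was not run.

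Values were raised by 95.2 so that the lowest was 16, taken to log2 and quantile normalized with limma 3.58.1 in R 4.3.3. This followed the branch laid down for background-subtracted values without normalization, and the branch was taken after looking at the table and before any model was fitted. The planned detection values could not be used, so a probe was taken as detected above 1.64 times the noise of its array, the root mean square of the values below 0. This substitute was chosen after seeing the data. Probes detected on at least 5 of 10 arrays, whatever their group, were kept, which left 10225 probes. The SD of log2 differences between pairs of arrays ran from 0.24 to 0.65, so no array was a copy of another.

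The deposited table has probe identifiers and no gene names. The number inside an identifier was matched to the gene identifiers of a mouse gene table of assembly GRCm38.p6, of which no coordinates are given. That this number is a gene identifier is an inference, tested as follows. Of 9523 probes with 1 or 2 leading zeros and a number of at least 11000, 93.3% matched a gene, against 41.9% for shifted numbers. In a range of larger numbers that holds few genes the shares were 95.6% and 12.4%, over 1402 probes. Probes without a leading zero matched no more often than shifted numbers (10.3% and 10.2% of 10988) and stayed unnamed. The 3 probes so named for hepatocyte markers had a median brightness percentile of 99.5, the 4 for pancreas and gut markers 11.4, and the 1 for skeletal muscle 2.48. In all 8893 probes were named, 8884 by number and 9 by an accession inside the identifier, for 7413 genes, and 15155 stayed unnamed. Of the kept probes 4065 were named, for 3731 genes.

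Groups were compared with limma's linear model and moderated test (default prior, no trend, two-sided), with Benjamini-Hochberg adjustment over the 10225 kept probes and a threshold of 0.05. The prior added 3.03 degrees of freedom for a total of 11.0. The Gyk probe was also tested by a two-sided exact permutation test of the difference of mean log2 values over 252 assignments. Intensities are means of the deposited values, and log2 values and changes are those after normalization. The constant added before log2 pulls log2 changes toward 0, most strongly for dim probes. Gene lists were tested with limma's camera (preset correlation 0.01, one probe per gene, the brightest, among kept named genes), with camera at an estimated correlation, and with fry, for lists with at least 4 kept genes. The 36 lists hold 578 genes, of which 232 had a named probe.

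The rule named Gyk, then up to 12 genes per direction with the largest change among those past the threshold without overlap between groups, filled up by the smallest p among named genes if under 24 probes passed, and up to 4 members with the smallest p for each list described. As 0 probes passed, all 24 genes came from the filling. Other genes were chosen after their values were seen: Lpin2, and, among probes called without 2 arrays, Psme4, Serpina3m, Ero1b, Slc35d1 and Serpinh1, and the blood and antibody probes Hba-a1, Hbb-b1, IGKC, IGHG2C, IGHA and IGHM. Ighm, S100a9 and Cd3e were also chosen then and are given as intensities alone. Liver holds Kupffer and endothelial cells, and of 5 Kupffer cell genes with a probe 4 were detected on at least 5 arrays, and of 5 endothelial genes 5.

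The other settings tried were normexp background correction, 50 in place of 16 as the lowest value, median scaling, cyclic loess, the deposited values without further normalization, no filter, detection at p under 0.01 on all 10 arrays, the leading number of the sample title as a block and within the numbers 1 and 2, a trended and robust prior, array weights, and leaving out each sample in turn. These settings, the groups, lists, tests, thresholds and the rule for naming genes were set before the data were examined, apart from the detection threshold. Samples were left out after normalization and filtering. Treating 2 arrays that stood apart as a block, leaving them out, and using all kept probes as the background of the list test were added after seeing the data. For 100 of the 126 distinct splits of the 10 samples into 5 and 5, drawn with a fixed seed and including the real one, the tests were repeated.

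The steps were tested on simulated data with 10212 probes and 5 against 5 samples. Of 95 kept probes changed by a log2 of 0.5, 55.8% were recovered, and of 89 kept probes changed by a log2 of 1, 92.1%. Changed probes that failed the detection filter were not counted, so the shares over all changed probes were lower. Of 142 probes called 7 were false, and a list shifted by a log2 of 0.5 was recovered with an adjusted p of 4.29e-26 and 0 other lists. The simulated probes were drawn independently, and the list shift was added after normalization. The correlation among genes and the distance of 2 arrays in the real data were thus absent, so this says little about the list tests here. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.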

Results

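Gene expression was measured in the livers of 10 female mice aged 23 weeks, 5 heterozygous for Gyk and 5 wildtype of the C57Bl/6J strain, with 1 Illumina bead array per mouse. Gyk is the X-linked gene of glycerol kinase, the enzyme that phosphorylates glycerol so that it can enter glycerolipid synthesis and glucose production. Each array gave 1 intensity for each of 24048 probes. The median intensity of an array lay between 14 and 24, and between 9991 and 10859 probes per array stood above the noise. The labels describe separate mice, and the number of arrays limits the precision. Gene names are those that a match of the number inside a probe's identifier to a gene table gave, for 8893 probes.

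Gyk was lower in heterozygous than in wildtype liver. In female cells 1 X chromosome is silenced, so a heterozygous liver is a mixture of cells that use the altered and the intact copy. The Gyk probe (scl0014933.2_154-S, gene symbol Gk in the gene table) had an intensity of 319.7 ± 90.1 (SD, n = 5) in heterozygous and 559 ± 209 (SD, n = 5) in wildtype liver. After normalization the log2 values were 8.66 ± 0.29 and 9.31 ± 0.38, a log2 change of -0.65 with an SE of 0.19. With 95.2 added to each value, the heterozygous level was 63.7% of the wildtype level, with a 95% confidence interval of 47.7% to 85.1%. The added constant pulls ratios toward 1, and the ratio of the mean deposited intensities was 57.2%.

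All 5 normalized heterozygous values lay below all 5 wildtype values, and a two-sided exact permutation test over 252 assignments gave p = 0.00794, the smallest p these groups allow. With arrays scaled by their medians in place of quantile normalization, the highest heterozygous value passed the lowest wildtype value and the exact permutation p was 0.0238. With cyclic loess, and with the deposited values left as they were, the groups also overlapped and the exact permutation p was 0.0159. Among all 10225 probes tested with limma the adjusted p of Gyk was 0.332, and its unadjusted p ranked 156. Adjusted over the list alone it was 0.0396 among 7 genes of glycerol and glycerolipid synthesis. It was 0.0227 in the list of Gyk and its neighbours on chromosome X, 4 genes with Gyk included. Values adjusted over a list alone, here and below, are not corrected for the 22 lists tested. Without wildtype replicate 1, which had the highest Gyk intensity at 914, the log2 change was -0.50. The other Gyk probe (scl014933.1_35-S) was detected on 0 arrays of either group. Where the measured probe lies relative to the altered part of the gene was not given in the sources used here.

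**Figure D1:**
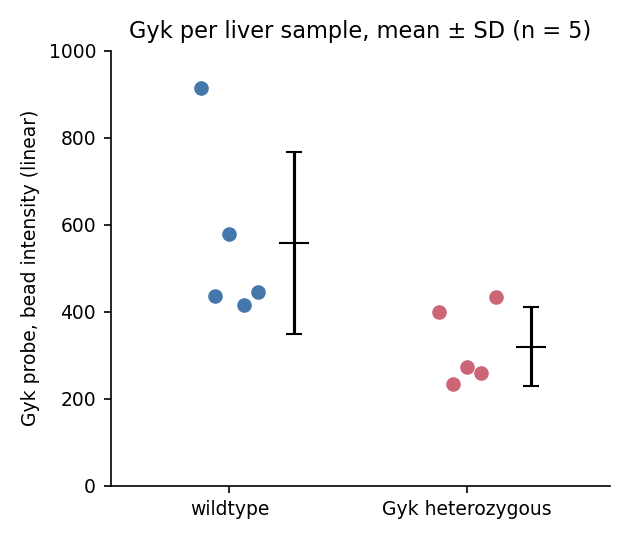
Intensity of the Gyk probe (vertical axis, linear bead intensity) in each wildtype and heterozygous liver sample, with the mean and SD of 5 samples beside the points. The heterozygous mean was 319.7 and the wildtype mean 559, and before normalization the highest heterozygous value, 433, lay above the lowest wildtype value, 416.

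The comparison of all probes asked which transcripts differ in the liver when 1 copy of Gyk is altered. Pex11g, which codes for a membrane protein of peroxisomes, the organelles that shorten very long fatty acids, had the smallest p. Its intensity was 752 ± 59.5 (SD, n = 5) in heterozygous and 481 ± 46.9 (SD, n = 5) in wildtype liver. The log2 change of Pex11g was 0.56 with an SE of 0.08, and its limma adjusted p was 0.157. Por, the reductase that passes electrons to the cytochromes P450, had an intensity of 2259.6 ± 142 (SD, n = 5) in heterozygous and 3914 ± 1127 (SD, n = 5) in wildtype liver, a log2 change of -0.68 with an SE of 0.17.

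No probe passed, so none of these genes was called: limma gave 0 probes at an adjusted p under 0.05 and 0 at an adjusted p under 0.10, against 1221 probes at an unadjusted p under 0.05. Of the 1221 probes 742 were higher and 479 lower in heterozygous liver, and those with a name stood for 458 genes. The share of higher probes was 60.8%, but 44.1% with the deposited values left without normalization and 48.7% without wildtype replicate 1. They made up 11.9% of the kept probes, where 511 probes would be reached by chance. The heterozygous and wildtype values did not overlap for 181 probes, 1.77% of those kept, where chance gives 0.794%. A log2 change above 1 in size was measured for 11 probes.

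The count of 0 called probes depended on wildtype replicate 1. Without wildtype replicate 1, 435 probes passed. Without both Gyk heterozygous replicate 1 and wildtype replicate 1, whose arrays stood apart from the other 8, 206 probes passed. With array weights 410 probes passed. Each other single sample left out gave 0 called probes, with 746 probes at an unadjusted p under 0.05 without wildtype replicate 4 and 759 without wildtype replicate 5. With the leading number of the sample title as a block limma gave 0 called probes and 506 probes at an unadjusted p under 0.05, and within the numbers 1 and 2 it gave 0 and 449. That number was 1 or 2 in the heterozygous samples and 7 in wildtype replicates 3, 4 and 5 alone, so it cannot be separated from the group in those samples. Both title number settings thus compare the heterozygous samples with wildtype replicates 1 and 2 alone. They give the same log2 changes and are not separate checks. Without wildtype replicate 1, only wildtype replicate 2 shares a title number with heterozygous samples. The 435 and 206 probes therefore cannot be told apart from an effect of the title number. The model with array weights held no title number either, so the same limit holds for its 410 probes.

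**Figure D2:**
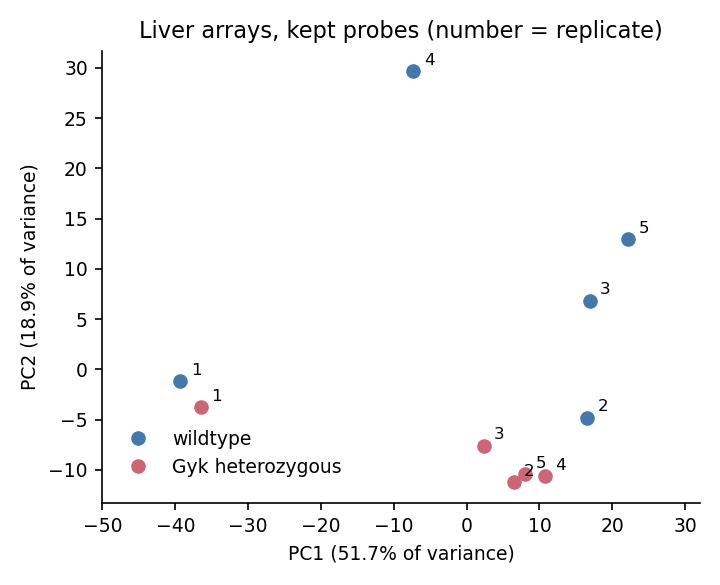
The 10 liver arrays on the first and second principal components of the kept probes (axes in component units, the first with 51.7% of the variance), colored by group and numbered by replicate. Gyk heterozygous replicate 1 at -36.5 and wildtype replicate 1 at -39.3 on the first component stand apart from the other 8 arrays.

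Among the named genes, the 12 with the smallest p in each direction are given as values that did not pass. They were not tested as groups. Shoc2, a scaffold of the Ras pathway, was higher in heterozygous liver, with a log2 change of 0.76 (SE 0.19) and an intensity of 366 ± 110.2 (SD, n = 5) against 170.1 ± 47.1 (SD, n = 5). Ulk2, a kinase that starts autophagy, had a log2 change of 0.32, and Uri1, a chaperone partner, 0.56. Gng10, a G protein subunit, had 0.48, Gpbp1 0.48, Ccdc25 0.43, Zranb1 0.36, and the X-linked ribosomal gene Rps4x 0.51. The mitochondrial iron-sulfur gene Glrx5 had a log2 change of 0.35 and the dehydrogenase gene Dhrs7 0.42. Daam1 had 0.26 and was detected in 0 of 5 wildtype samples. With 95.2 added to each value and wildtype values raised to the lowest detected signal of their array, the mean was 1.06-fold higher in heterozygous liver. This ratio of means carries no sampling error and is no confidence bound. The intensity of Daam1 was 36.7 in heterozygous and 17.1 in wildtype liver, where detection thresholds of the arrays ran from 22.0 to 41.2.

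Among the genes lower in heterozygous liver, Mrpl19 had a log2 change of -0.39, Mrpl49 -0.37 and Mrpl33 -0.27. Smpd2, a sphingomyelinase, had a log2 change of -0.58 with an SE of 0.14, and the glutathione transferase gene Gstt2 had -0.51. Emc8, of the complex that inserts membrane proteins, had -0.42, and the transport gene Trappc13 had -0.43. Prmt7 had -0.41, Nudt22 -0.40, Szrd1 -0.36 and Smim4 -0.35. The adjusted p was 0.332 for every one of the 24 genes except Pex11g. Their groups did not overlap except for Shoc2, Rps4x, Trappc13 and Nudt22. In simulated data of 5 against 5 samples, with probes drawn independently, the same test recovered 53 of 95 kept probes changed by a log2 of 0.5. It recovered 82 of 89 kept probes changed by a log2 of 1, and changed probes that failed the detection filter were not counted.

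**Figure D3:**
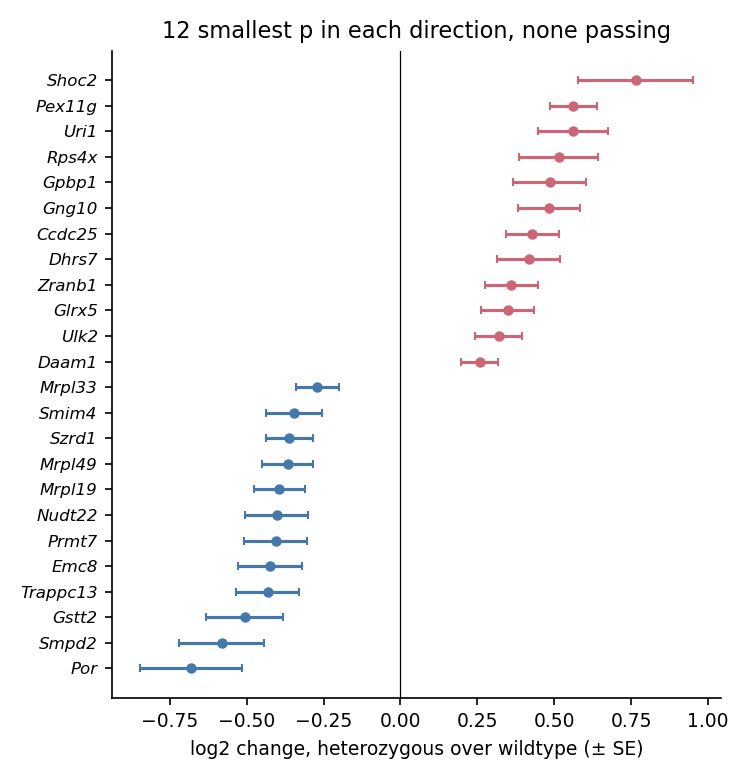
Log2 change between heterozygous and wildtype liver (horizontal axis, with SE) of the 12 named genes with the smallest p in each direction, 5 samples per group. The values run from -0.68 for Por to 0.76 for Shoc2, and the smallest adjusted p is 0.157 for Pex11g.

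The gene lists asked whether pathways around glycerol kinase, other liver programmes or cell type markers shifted together. Genes of the list for glycerol and glycerolipid synthesis, which take up glycerol, turn it over and build or break down glycerolipids, were lower in heterozygous liver for 6 of 7 members, with a mean log2 change of -0.29 and a median of -0.32. Besides Gyk, the lower members with the smallest p included Gpd2, which oxidizes glycerol phosphate in mitochondria, at -0.33, the acyltransferase gene Gpat4 at -0.32, the triglyceride lipase gene Pnpla2 at -0.23 and the phosphatase gene Lpin2 at -0.48. The list did not pass: camera gave an adjusted p of 0.0558 (unadjusted p = 0.00254), the adjusted p was 0.318 with an estimated correlation, and fry gave 0.0645. Its camera adjusted p with the preset correlation ranged from 0.00202 to 0.241 over 23 alternatives, of which 8 put it under 0.05, among them those without Gyk heterozygous replicate 3 (0.0217), wildtype replicate 2 (0.0363) and wildtype replicate 4 (0.0105). With an estimated correlation the adjusted p in these 8 cases was 0.132 to 0.425. Lpin2 had a log2 change of 0.0498 with the title number as a block.

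Targets of PPAR-alpha, the receptor that turns on fatty acid oxidation, were lower for 5 of 8 members, with a mean log2 change of -0.24 and a camera adjusted p of 0.241. Their largest values were in Crat (-0.61), Angptl4 (-0.59), Pex11a (-0.58) and Cyp4a10 (-0.40), and Angptl4, a secreted inhibitor of lipoprotein lipase, had 0.0432 adjusted over the list alone. Fatty acid synthesis was higher for 5 of 6 members, with a mean log2 change of 0.14, including Acaca at 0.24, Fasn at 0.24 and Acss2 at 0.21. Markers of Kupffer cells, the macrophages of the liver, were higher for 4 of 4 members with a mean of 0.27, including Csf1r at 0.41 and C1qb at 0.36. Their camera adjusted p was 0.210, but 0.0495 without Gyk heterozygous replicate 3 and 0.0192 without wildtype replicate 2, and with an estimated correlation 0.768 and 0.785. Without wildtype replicate 2 the mean of these markers was 0.43. Genes biased toward female liver were higher for 8 of 9 members with a mean of 0.20, and Cyp2b9 had a log2 change of 0.48 and 0.0357 adjusted over the list alone. The mean of the female-biased genes was -0.0454 with the title number as a block. The camera adjusted p of fatty acid synthesis, Kupffer cell markers and female-biased genes was 0.210. With an estimated correlation the adjusted p of these lists and of the PPAR-alpha targets was 0.945.

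Probes of other blood and immune cells made up no tested list, and none passed. The hemoglobin genes Hba-a1 and Hbb-b1, which code for the oxygen carrier of red blood cells, had log2 changes of -0.33 and -0.31 (adjusted p 0.758 and 0.632). Without wildtype replicate 5 these were -0.01 and -0.11, and with the title number as a block 0.379 and 0.00575. Of 4 antibody probes for constant regions, named as in their identifiers, IGKC had -0.77, IGHG2C -0.84, IGHA -0.19 and IGHM -0.07 (adjusted p 0.421, 0.349, 0.394 and 0.958). IGHG2C was dim in heterozygous liver and was detected on only 7 arrays. Its intensity was 28.6 ± 18.2 (SD, n = 5) in heterozygous and 157 ± 148 (SD, n = 5) in wildtype liver, with a highest wildtype value of 410. Its heterozygous mean lay inside the range of the arrays' detection thresholds, 22.0 to 41.2. Without wildtype replicate 1 the adjusted p of IGKC was 0.0405 and that of IGHG2C 0.0480, and with array weights IGHG2C had 0.0449. Without wildtype replicate 5 the log2 change of IGHG2C was -0.55 and that of IGKC -0.54, and with the title number as a block they were -0.22 and -0.02. The sign of IGHM changed between alternatives. A further antibody probe, matched to Ighm by its number, had an intensity of 559.5 in heterozygous and 636.8 in wildtype liver. S100a9 and the T cell gene Cd3e had higher mean intensities in heterozygous liver, 57.5 against 39.8 and 44.1 against 28.6, given without a test. Both probes were dim, as the detection thresholds of the arrays ran from 22.0 to 41.2. In wildtype liver S100a9 was detected in 4 and Cd3e in 2 of 5 samples, and in heterozygous liver both in 5 of 5.

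Heat shock genes had values on both sides of 0, and the 4 with the smallest p did not pass among all probes (adjusted p 0.332 to 0.379). The mitochondrial chaperones Hspd1 and Hspe1 had log2 changes of 0.40 and 0.42, and the cytosolic Hsp90aa1 and Hspa8 had -0.62 and -0.21. All 4 were under 0.05 adjusted over the list alone, with a smallest value of 0.0183, while the camera adjusted p of the list was 0.957 and that of fry for change in either direction was 0.218. Adjusting over the list alone does not correct for the 22 lists, and 11.9% of all kept probes had an unadjusted p under 0.05. Among 13 genes of xenobiotic metabolism, Por (0.0232) and Cyp2b9 (0.0258) were under 0.05 adjusted over the list alone. Ribosomal proteins were higher for 7 and lower for 8 of 15 members, with a median of -0.00, a mean of 0.11, an upward test and an adjusted p of 0.269. That mean was 0.05 with median scaling and 0.03 with the deposited values (adjusted p up to 0.967). Rpl7 (0.73), Rpl10 (0.35) and Rps3 (0.31) had the smallest p of that list. In glycolysis Pgk1 had 0.48, Eno1 0.39 and Tpi1 -0.21. Uqcrc1, of oxidative phosphorylation, had -0.26, and Insig1, of cholesterol synthesis, had 0.40. The probes of families with near-identical members, such as Cyp2b9, Cyp4a10, Gstt2 and Hspa8, were not told apart from their relatives.

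Of the 22 lists tested, 0 passed with camera, 0 with an estimated correlation, 0 with fry and 0 with its test of change in either direction, against 4 at an unadjusted camera p under 0.05. The interferon response was higher for 7 of 8 members (adjusted p 0.582, and without Gyk heterozygous replicate 3 0.0493, or 0.768 with an estimated correlation), lipoprotein secretion for 5 of 7 (0.787) and acute phase proteins for 5 of 7 (0.833). Cholesterol synthesis was lower for 7 of 11 members (0.933) and insulin and IGF signalling for 6 of 6 (0.957). The adjusted p was 0.957 for glycolysis, xenobiotic metabolism, oxidative phosphorylation, endothelial markers, the urea cycle and amino acid metabolism, oxidative stress, male-biased liver genes, the neighbours of Gyk on chromosome X, the cell cycle and MHC class II. The mean changed sign in at least 1 of 23 alternatives for 13 of the 16 lists with an unadjusted camera p of 0.1 or more. Median and mean differed in sign for ribosomal proteins, oxidative stress, glycolysis, the neighbours of Gyk and xenobiotic metabolism, and in oxidative phosphorylation the test pointed down while both were above 0. Another 14 lists had fewer than 4 kept genes and were not tested. Endoplasmic reticulum stress, lipid droplets, hepatocyte, erythroid and stellate cell markers had 3 kept genes each. Gluconeogenesis, bile acids, the circadian clock, immediate early genes, adipocyte and lymphocyte markers had 2 each, cholangiocyte and pancreas and gut markers 1 each, and skeletal muscle markers 0.

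**Figure D4:**
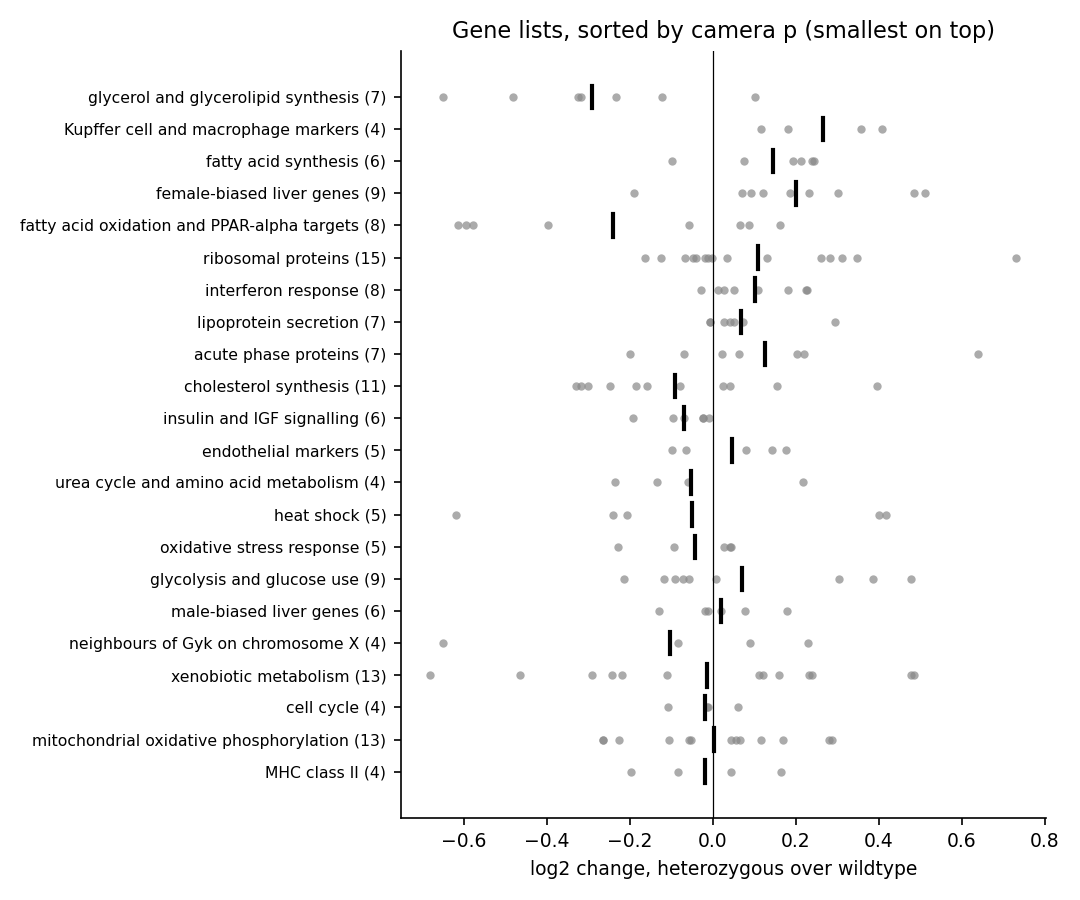
Log2 change between heterozygous and wildtype liver (horizontal axis) of each member of the 22 lists tested (gray points) with the list's mean (black bar), the smallest camera p on top and the number of genes in parentheses. Glycerol and glycerolipid synthesis has the smallest camera p with a mean of -0.29, and no list passed an adjusted p of 0.05.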

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

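The tests of the noise on 2 arrays and of the 2 chips were chosen only after the result was seen, as were the alternatives that set these arrays apart. On the first principal component of the kept probes, Gyk heterozygous replicate 1 lay at -36.5, far from the other heterozygous samples at 2.33 to 10.7. Wildtype replicate 1 lay beside it at -39.3. Their arrays correlated at r = 0.991 across probes with each other and at 0.934 to 0.967 with the other 8, which correlated at 0.965 to 0.990 among themselves. Probes are not independent replicates. Between these 2 arrays and the other 8, 396 probes (3.87%) differed by a log2 above 1 in size, 264 higher and 132 lower.

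Single samples also stood far from the rest of their group in 9 probes, given as normalized log2 values. In wildtype replicate 1, Ndufs3 of mitochondrial complex I was 12.02 (others 11.19 to 11.35), the endoplasmic reticulum oxidase gene Ero1b was 8.78 (others 7.28 to 7.69), the collagen chaperone gene Serpinh1 was 8.34 (others 9.12 to 9.41), and Cyp4a10 was 15.30 (others 15.09 to 15.14). In Gyk heterozygous replicate 1, the glycolysis gene Eno1 was 10.94 (others 11.25 to 11.36) and the sphingomyelinase gene Smpd2 was 9.98 (others 10.07 to 10.08). In wildtype replicate 4, Gstt2 was 11.89 (others 11.36 to 11.42) and Mrpl49 was 11.31 (others 10.94 to 11.01). In Gyk heterozygous replicate 4 the antibody probe IGKC was 10.35 (others 9.32 to 9.56). Of 148 groups tested, 10 held such a sample. Chance gives about 1 in 20 where measures are not picked by their values, which does not hold here. Ero1b and Serpinh1, for example, were named because they were called without wildtype replicate 1 and Gyk heterozygous replicate 1, so their distance in wildtype replicate 1 follows from that choice.

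None of the technical explanations tested for the 2 arrays' distance was excluded. Higher background noise stayed open: the noise of Gyk heterozygous replicate 1 was 18.2, inside the 13.4 to 19.7 of the other 8 but the highest of its group, and that of wildtype replicate 1, 25.1, was above all others. Against it, these arrays did not have fewer detected probes: 10859 and 10149, where the other 8 had 9991 to 10502. An effect tied to single probes, such as a chip or hybridization step might give, stayed open: across 316 genes with a pair of kept probes, the shift of these arrays correlated at r = 0.322 between the probes of a gene. That is above the -0.239 to 0.212 reached with genes shuffled, and below the 0.5 set for a difference in the RNA itself. The group difference, measured the same way, gave 0.394. Whether the 2 arrays sat on the chip that holds 2 arrays stayed open: no label ties chip positions to samples, and matching them by their values was not tried. The 2 samples come from different groups and share the title number 1, whose meaning is not given. Wildtype replicate 1 is the only wildtype sample with it, while Gyk heterozygous replicates 2 and 3 have it and did not stand apart. No biological explanation was tested.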

How the results depend on the processing

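Gyk stayed lower in all 23 alternatives, from -0.84 with the title number as a block to -0.50 without wildtype replicate 1, and its limma adjusted p stayed above 0.05 (0.0509 to 0.913). The count of called probes was 0 except for 410 with array weights, 206 without the 2 arrays that stood apart (chosen after seeing the data), 435 without wildtype replicate 1 in a leave-one-out range of 0 to 435, and 1221 at an unadjusted threshold. The count at an unadjusted p under 0.05 was 1911 without a filter, where more probes were tested, 2342 with array weights and 2118 without the 2 arrays. It was 506 with the title number as a block and 449 within numbers 1 and 2. Those 2 settings both compare the heterozygous samples with wildtype replicates 1 and 2 alone. On leaving out each sample the count was 746 (without wildtype replicate 4) to 2354 (without wildtype replicate 1). The list count was 1 with median scaling, the deposited values, no filter, detection at p under 0.01 on all 10 arrays, the 2 arrays as a block, or all kept probes as background (the last 2 chosen after seeing the data), and 0 to 3 on leaving out each sample. It was 3 without Gyk heterozygous replicate 3, 2 without wildtype replicate 2 and 1 without wildtype replicate 4, and with an estimated correlation 0 of all these 12 calls held (adjusted p 0.132 to 0.785). The estimate was 0.538 to 0.760 for the Kupffer cell and interferon calls and -0.0425 to 0.0865 for the glycerol calls. For several glycerol calls it lay below the preset 0.01, so a higher correlation was not what raised their adjusted p. Lpin2 reversed to 0.0498, Hba-a1 to 0.379, Hbb-b1 to 0.00575, IGHM to 0.0733 and the female-biased list to -0.0454 with the title number as a block and within numbers 1 and 2, and IGHM ran from -0.352 (without Gyk heterozygous replicate 4) to 0.0885 (without Gyk heterozygous replicate 3). Beyond the number of probes or samples, the cause was not tested. None of the 24 genes named by rule turned sign, and 22 passed 0.05 with array weights, 16 without wildtype replicate 1 and 8 without the 2 arrays. These genes were picked by the smallest p in the same samples, so this is no separate support. Of 38 other named genes followed through the alternatives 4 turned sign. The chip as a block was not run. Signal over background limits the dim probes: 7065 probes met the stricter detection on all arrays.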

Other observations

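The alternatives with the 2 arrays apart, the test by title number, the count of splits over all lists and the look at splits that part the 2 arrays were chosen only after the result was seen, as was the estimated correlation in the test without Gyk, and the other splits of the samples and the rest of that test were not. Without Gyk heterozygous replicate 1 and wildtype replicate 1, 206 probes passed limma's adjusted p of 0.05, 176 higher and 30 lower in heterozygous liver. Those with a name stood for 53 genes. These genes were not tested as groups, and the heat shock list had a camera adjusted p of 0.874 in these 8 samples. Higher were the proteasome activator gene Psme4 (log2 change 1.12), the disulfide oxidase gene Ero1b (0.83), and the mitochondrial chaperone genes Hspd1 (0.47) and Hspe1 (0.49). The others of the fixed lists were Rpl7 (0.92), Pgk1 (0.61), Cyp2b9 (0.58) and Ndufs3 (0.38), and the secreted protease inhibitor gene Serpina3m had 0.83. Smpd2 (-0.69), the nucleotide sugar transporter gene Slc35d1 (-0.67) and Serpinh1 (-0.56) were lower. The adjusted p of these 12 genes ran from 0.0398 to 0.0494. With all 10 samples the 206 probes had the same sign and 175 had an unadjusted p under 0.05. The 8 samples that picked these probes are among the 10, so this is no separate support. Of the wildtype samples left, only replicate 2 shares a title number with heterozygous samples, so these calls cannot be told apart from an effect of that number. As the 2 samples were also picked from the data, the calls are a hypothesis for other mice.

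The list for glycerol and glycerolipid synthesis did not pass in heterozygous liver (camera adjusted p = 0.0558, and adjusted p = 0.318 with an estimated correlation), and it was asked whether its lower values rested on Gyk. Among 100 splits of the samples, 4 gave a camera p as small as the real 0.00254 for this list, the real one included. The smallest of the others was 6.14e-05. Over all 100 splits, chance could be excluded for this list only if it were the only list tested. All 4 splits parted the 2 arrays that stood apart, as the real one does, and 56 of the 100 splits did so. Among those 56 the share was above 0.05, so chance was not excluded even for this list alone. The real 0.00254 was the smallest p of 22 lists. In 70 of the 100 splits, the real one included, some list had a p as small, so chance was not excluded for the smallest p. Without Gyk the camera p of the other 6 genes was 0.0166 (adjusted p = 0.210), and with an estimated correlation it was 0.0812 (adjusted p = 0.945). The bound of 0.05 set for this test did not name the correlation, and only the preset one met it, so whether Gyk alone carries the list stays open. Over the alternatives the adjusted p of the list ran from 0.00202 to 0.241. A response to less glycerol kinase was not tested and stays open, as does an effect tied to the title numbers, whose meaning the labels do not give.

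For the excess of probes with an unadjusted p under 0.05 chance was not excluded over all splits: of 100 splits 11 gave as many as the real 1221, and the highest of the others gave 2320. The 10 others all put the 2 arrays that stood apart in the same group, which points to a structure of the samples. Among the 56 splits that parted these arrays, as the real one does, 1 reached 1221, the real one, and the others had a median of 170 and a highest count of 1076. Of these, the 7 that also kept the samples numbered 7 together, as the real one does, gave 543 to 1076, and the other 48 gave at most 388, so the excess went with the title number as well. With the 2 arrays as a block the real split gave 1823. The real counts of called probes and called lists were 0, which any split reaches (100 of 100 for each, with 79 probes and 8 lists in the highest other), so chance was not excluded, and there was no call to test. The title number stays a candidate source: with the 2 arrays as a block, the heterozygous samples gave 799 such probes against wildtype replicates 1 and 2, and 879, 1837 and 1259 against wildtype replicate 1 with replicates 3, 4 and 5, where chance gives 511. The title number and the Gyk genotype cannot be told apart in wildtype replicates 3 to 5, since no heterozygous sample has their number.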
